A study of Mus musculus with 6 samples.

How the data were processed

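RNA was measured in colon crypts, the epithelial glands of the large intestine, from 6 male C57BL/6 mice. Mice 1 to 3 of the control group drank distilled water and mice 1 to 3 of the other group received 3.5% dextran sulfate sodium (DSS), a polysaccharide that injures the colon epithelium and is used to model colitis, for 7 days. Per the labels' protocols, total RNA from the crypts was purified with Qiagen reagents and made into libraries with the ALFA-SEQ RNA library kit. The groups and replicate numbers were taken from the sample titles. The random division of the mice into groups of 3 is stated in the series design, so each library stood for 1 mouse.

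The submitters' processing notes name fastp 0.23.2, Bowtie2 2.4.5 and HISAT2 2.2.1 without their roles. The read counter, the genome build, the annotation and the strand setting were not given in the sources used here, and no coordinates are printed for that reason. The deposited count table holds whole-number counts per gene, not normalised, for 23766 genes, of which 1550 were at 0 in all 6 libraries. The deposited FPKM table holds the same genes as fragments scaled by gene length and library size, computed by the authors. Dividing counts by FPKM gave a gene length that differed by more than 5 percent between libraries for 916 of the 4492 genes with 500 or more counts in every library. A number of lines without values, 25 in each of the tables, continued an annotation text broken off in the line above and were left out. Every remaining line named a gene.

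Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its minimum count of 10, which left 13418 genes, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test of glmQLFit and glmQLFTest at the defaults of this version (legacy = TRUE). A run with the newer method of the same version preceded it by mistake, and that method is given as an alternative added after the data were seen. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are DSS minus control. Their standard errors were obtained by dividing the fold change by the root of the F statistic, and 95% intervals from the moderated degrees of freedom. Levels are TMM-normalised CPM, counts scaled to library size, given as mean ± SD over 3 libraries.

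Before the data were examined, 46 gene lists were fixed for Wnt and SOX genes, epithelial lineages, other cell types of the colon wall, inflammation, barrier, metabolism and RNA quality. Of their 1152 members, 1065 were found by name and 13, the mitochondrial genes, by Entrez identifier through the RefSeq gene table of GRCm38.p6, while 74 were not matched. The 41 lists with at least 5 tested genes were tested with camera from limma 3.58.1 at the preset correlation of 0.01, two-sided, with adjustment over these 41 lists, and again with an estimated correlation and with fry. Genes of a list were also adjusted over the list alone. Genes named in the text followed a rule fixed at the same time: Sox9, Ctnnb1, Axin2, Lgr5, Tnks and Tnks2 always, then up to 10 genes per direction with the largest change among those past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, then up to 4 members of each list with the smallest p. Other named genes are marked as chosen after their values were seen.

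The functions were tested on simulated counts for the comparison of DSS with control, with the means, library sizes and dispersions of these libraries. Among 13146 genes, 200 were changed. These were drawn from genes with a mean log2 CPM of at least 2, so recovery at lower levels was not covered. Of the genes changed 4-fold and 8-fold, edgeR recovered 92% and 97% with 7 false calls, and DESeq2 1.42.0 recovered 97% and 100% with 39 false calls. With no gene changed, edgeR made 0 and DESeq2 1 call among 13125 genes. The simulated genes varied independently of each other, which real genes do not. The shares recovered are therefore no estimate of how many real changes of these sizes were found. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom of their counts was at least 34.3.

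Alternatives fixed before the data were examined were DESeq2, limma-voom, other scaling (RLE, upper quartile, library totals, the summed counts of general epithelium genes), other count filters, a robust prior, the replicate number as a block, leaving out each library, limma with a trend on log2 FPKM with pseudocounts of 1 and 0.1 and a mean FPKM of at least 0.5 or no filter, a threshold of 0.01, a test against a log2 fold change of 1, and protein-coding genes alone by the RefSeq gene table. After the results were seen, lists of clock genes, of genes induced by tissue dissociation and of genes of the distal gut axis, and the KEGG pathways annotated in the tables, were tested in addition. The list of distal gut axis genes was written before any value of its genes had been seen. Principal components used log2 CPM with a prior count of 2. Single values per library were compared by exact permutation tests, two-sided, in Python 3.11.15 with scipy 1.17.1. With 3 against 3 libraries these cannot give a p below 0.1. Shares of counts carry 95% Wilson intervals, which cover counting error only.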

Results

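The series measured RNA in colon crypts of 3 control mice given distilled water and 3 mice given 3.5% DSS for 7 days. Its title names Wnt/β-catenin signalling, the transcription factor SOX9 and the tankyrase inhibitor XAV939 in DSS colitis. The libraries compare crypts with and without DSS, and no library analysed here received the inhibitor. The count totals were 21260437, 20087660 and 19892566 in control replicates 1, 2 and 3, and 18970885, 17440642 and 19737376 in DSS replicates 1, 2 and 3. Between 17228 and 17914 genes had at least 1 count in a library.

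Mitochondrially encoded transcripts made up 22.6% ± 8.12 of counts in control and 13.6% ± 2.93 in DSS libraries (SD, n = 3 each; exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible). The 95% Wilson interval of each share was at most 0.0194 percentage points to either side. Control replicates 1 and 2 held 29.4% and 24.7%, whereas control replicate 3 held 13.6%, within the 11.8% to 17.0% of the DSS libraries. The mucin Muc2, chosen here after its values were seen, took 3.97% ± 3.37 of counts in control and 2.70% ± 1.89 in DSS (exact permutation p = 0.7). In log2 CPM over all tested genes, control replicate 3 correlated with DSS replicate 1 at r = 0.964 across genes, which are not independent replicates. Its correlation was 0.938 and 0.931 with control replicates 1 and 2, and 0.921 and 0.946 with DSS replicates 2 and 3.

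**Figure D1:**
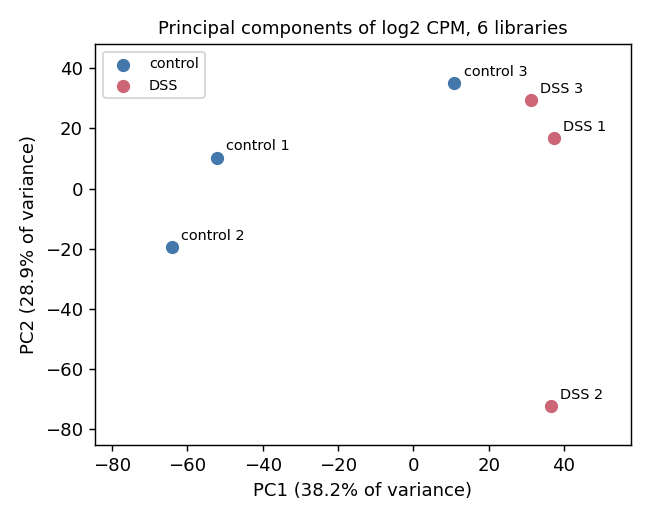
Principal components of log2 CPM for the 6 libraries, with the first component (38.2% of variance) on the x axis, the second (28.9%) on the y axis, and control and DSS libraries as points of different colours. Control replicate 3 lies at 10.9 on the first component, between control replicates 1 and 2 (-52.2 and -64.1) and the DSS libraries (31.4 to 37.4), and DSS replicate 2 lies apart on the second component at -72.2.

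The comparison of DSS with control asked which transcripts of the crypt differ after 7 days of DSS. Of 13418 genes tested with edgeR's quasi-likelihood test, 5 passed an adjusted p of 0.05, all lower in DSS and all changed by more than 1 on the log2 scale. Fosb, a subunit of the AP-1 transcription factor (Entrez 14282), fell from 203 ± 148 to 1.07 ± 0.248 CPM (log2 fold change -7.56, SE 0.606, adjusted p = 0.0069). The inducible HSP70 chaperone genes Hspa1a (Entrez 193740) and Hspa1b (Entrez 15511) fell from 495 ± 299 to 13 ± 3.07 CPM and from 801 ± 422 to 47.9 ± 6.78 CPM, with log2 fold changes of -5.25 (SE 0.528, adjusted p = 0.016) and -4.06 (SE 0.466, adjusted p = 0.028). These genes are near-identical copies, so the split of reads between them is uncertain. Tppp3, which encodes a tubulin polymerization-promoting protein (Entrez 67971), fell from 61.6 ± 38.5 to 1.51 ± 0.471 CPM (log2 fold change -5.35, SE 0.569, adjusted p = 0.019), and the predicted gene Gm10382 (Entrez 639281) from 31.1 ± 3.55 to 2.88 ± 0.969 CPM (log2 fold change -3.43, SE 0.331, adjusted p = 0.016).

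No gene passed as higher in DSS with edgeR, where the lowest adjusted p of such a gene was 0.095, that of Fbln1. At an unadjusted p under 0.05 there were 1400 genes, 578 of them higher and 822 lower. In 2245 genes, 16.7% of those tested, the 3 DSS libraries lay beyond the 3 control libraries on one side, against 10% by chance. DESeq2 called 281 genes, 97 higher and 184 lower, among them the 5 genes of the edgeR test, and limma-voom called 6, all lower. Without control replicate 3 the edgeR count was 1042 (553 higher, 489 lower), and without DSS replicate 1, 2 or 3 it was 0, with 962 to 1247 genes at an unadjusted p under 0.05. In these last fits the log2 fold changes stayed about as large, from -7.42 to -7.76 for Fosb, -5.11 to -5.55 for Tppp3, -5.08 to -5.42 for Hspa1a, -3.95 to -4.14 for Hspa1b and -3.18 to -3.60 for Gm10382. Their adjusted p lay between 0.058 and 0.16. Of the 177 genes named by the rule, 59 passed newly without control replicate 3, among them Fos, Clca1, Fcgbp, Avil, Ang4, Itln1, Mptx1, Fbln1, Ret, Nos2, Wfdc2, Egln3, Ano1, ND5, Ccn1, Fzd9, Gsdmc2, Gsdmc3 and Gsdmc4 in the directions of the comparison with all 6 libraries.

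**Figure D2:**
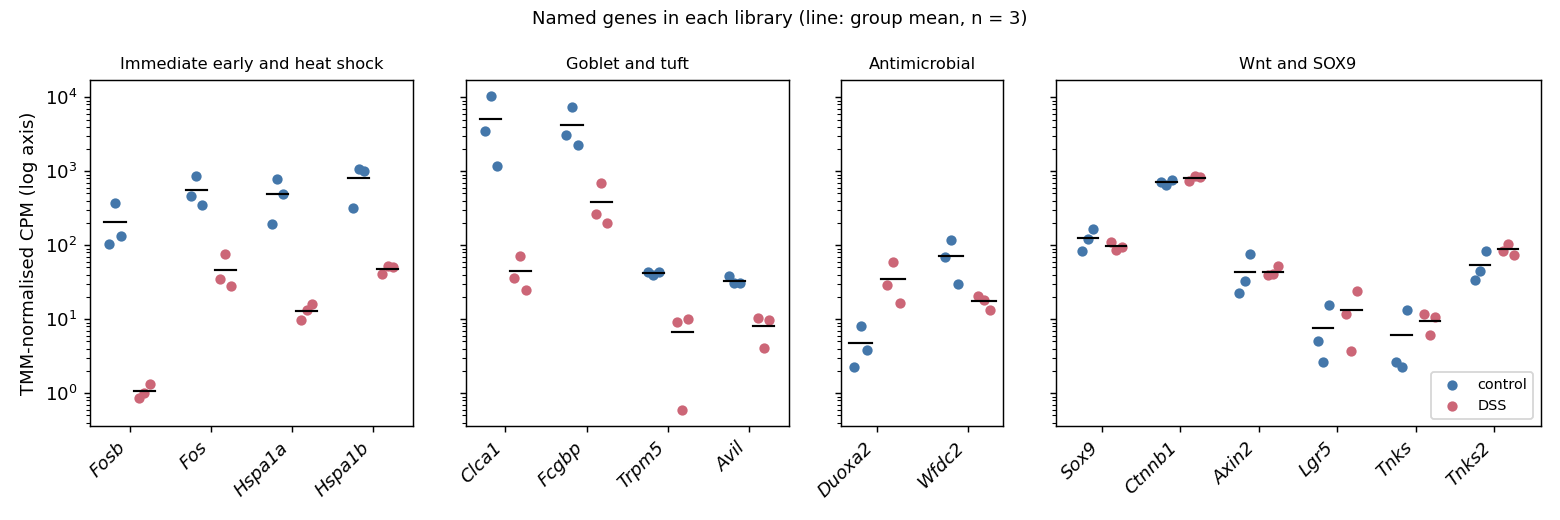
TMM-normalised CPM on a log axis for named genes in each library, with control and DSS libraries as points of different colours and the group mean of 3 libraries as a line. All DSS libraries lie below all control libraries for Fosb, Fos, Hspa1a, Hspa1b, Clca1, Fcgbp, Trpm5, Avil and Wfdc2 and above them for Duoxa2, whereas the groups overlap for Sox9, Ctnnb1, Axin2, Lgr5, Tnks and Tnks2.

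Among the gene lists, 8 of 41 passed camera at its preset correlation, and none of the 8 held with an estimated correlation (adjusted p of at least 0.51) or in fry (at least 0.34). Each of the other ways to split the 6 libraries into 3 and 3 gave between 10 and 17 lists at the preset. List calls given below for a left-out library, other scaling or another filter used the preset alone. They were not tested with an estimated correlation and carry the same limit. The immediate early and heat shock list, whose genes respond within minutes to growth factors, stress and handling, had the lowest p. Of its 19 tested members, 18 were lower in DSS, with a median log2 fold change of -2.15 (camera adjusted p = 9.4e-33, and adjusted p = 0.51 with an estimated correlation). Fosb, Hspa1a and Hspa1b passed over all genes, and 12 members, all lower, when adjusted over the list alone. In 12 members the groups did not overlap, against 16.7% of all tested genes. With an estimated correlation of 0.499 these members are not independent of each other. Fos, the partner of JUN in AP-1, was at 555 ± 261 CPM in control and 46.7 ± 26.5 CPM in DSS (log2 fold change -3.57, edgeR adjusted p = 0.078, DESeq2 adjusted p = 3.4e-15).

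The lists of tuft, goblet and deep crypt secretory cells were lower in DSS, and that of enteroendocrine cells did not pass. None of their genes passed over all genes with edgeR. All 17 tested genes of tuft cells, a chemosensory epithelial type, had lower values, with a median log2 fold change of -1.85 (camera adjusted p = 2.4e-14, and adjusted p = 0.57 with an estimated correlation). In 13 of the 17 the groups did not overlap, against 16.7% of all tested genes, and 8 passed when adjusted over the list alone. With an estimated correlation of 0.706 the tuft genes moved together, so these counts are not of independent genes. Trpm5, the cation channel of chemosensory signalling, was at 41.8 ± 2.07 CPM in control and 6.64 ± 5.26 CPM in DSS, and the actin-binding gene Avil at 33.2 ± 4.32 and 8.15 ± 3.55 CPM. Of 24 goblet cell genes 23 were lower (median -0.61, camera adjusted p = 4.8e-10, and adjusted p = 0.51 with an estimated correlation), and 6 passed adjusted over the list alone. Clca1, a secreted mucus component, was at 5074 ± 4876 CPM in control and 44.3 ± 24.2 CPM in DSS (log2 fold change -6.84, SE 0.893, adjusted p = 0.067), and Fcgbp, a mucus-binding protein, at 4255 ± 2734 and 385 ± 267 CPM (log2 fold change -3.47, SE 0.610, adjusted p = 0.11). DESeq2 called both, with adjusted p = 1.4e-10 and 0.0014.

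The 8 tested genes of Paneth and deep crypt secretory cells had a median of -1.36 (camera adjusted p = 0.037, and adjusted p = 0.51 with an estimated correlation), and 5 passed adjusted over the list alone, 3 lower and 2 higher. The call was lost without control replicate 2, where the median was -0.89 (adjusted p = 0.076), and without DSS replicate 3, where it was -1.30 (adjusted p = 0.062). The antimicrobial angiogenin Ang4 was at 104 ± 97.0 CPM in control and 2.52 ± 2.13 CPM in DSS, and the lectin Itln1 at 5.72 ± 5.62 and 0.279 ± 0.128 CPM. The pentraxin gene Mptx1 was at 2051 ± 2460 CPM in control, with 12187, 85441 and 11346 counts in replicates 1 to 3, and at 4, 159 and 0 counts in the DSS libraries. Matrilysin, Mmp7, went the other way, at 0.234 ± 0.213 CPM in control and 3.07 ± 1.79 CPM in DSS (DESeq2 adjusted p = 8.5e-04). The enteroendocrine list (18 genes) had a median of 0.24 (camera adjusted p = 0.52), and 2 members passed as higher when adjusted over the list alone. Without DSS replicate 2 the list passed as higher (median 0.38, adjusted p = 0.032). Its progenitor genes Neurog3 and Insm1 had log2 fold changes of 2.79 and 1.75, not past the edgeR threshold (adjusted p = 0.27 and 0.23) and past that of DESeq2 (0.0013 and 0.0096). Neurog3 was at 1.34 ± 0.325 CPM in control and 9.42 ± 10.1 CPM in DSS. Without DSS replicate 2, the highest library, its log2 fold change was 1.42.

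For the genes of the study's title, no difference passed the test with all 6 libraries. Sox9 was at 124 ± 42.3 CPM in control and 97.2 ± 12.6 CPM in DSS (log2 fold change -0.35, 95% interval -0.96 to 0.27, edgeR adjusted p = 0.66). Ctnnb1, which encodes β-catenin, was at 708 ± 62.7 and 805 ± 61.5 CPM (0.19, -0.30 to 0.68, adjusted p = 0.77). The Wnt feedback target Axin2 was at 43.8 ± 28.1 and 44.1 ± 7.15 CPM (0.0078, -0.91 to 0.92, adjusted p = 0.997). The stem cell receptor Lgr5 was at 7.71 ± 6.84 and 13.2 ± 10.2 CPM (0.77, -0.89 to 2.44, adjusted p = 0.72). The tankyrase genes Tnks and Tnks2 had log2 fold changes of 0.64 (-0.84 to 2.13) and 0.70 (-0.045 to 1.45), with adjusted p = 0.74 and 0.49. Without control replicate 3, Tnks and Tnks2 passed as higher in DSS, with log2 fold changes of 1.98 (adjusted p = 0.041) and 1.16 (adjusted p = 0.036). With any other library left out the lowest adjusted p was 0.70 for Tnks and 0.62 for Tnks2. The other values moved with single libraries too, without passing: without control replicate 3 the log2 fold change was -0.063 for Sox9, 0.66 for Axin2 and 1.79 for Lgr5, with adjusted p = 0.88, 0.13 and 0.18. Over the 6 left-out libraries it ranged from -0.57 to -0.063 for Sox9, from -0.31 to 0.66 for Axin2, from 0.018 to 1.79 for Lgr5, from 0.24 to 1.98 for Tnks and from 0.45 to 1.16 for Tnks2. With all 6 libraries, the intervals of Lgr5, Tnks and Tnks2 include a doubling, so at this spread a change of that size is not excluded.

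The 23 tested Wnt/β-catenin target genes, 12 higher and 11 lower, had a median of 0.0078 (camera adjusted p = 0.54). Sox4 and Tcf7l2, transcription factors of this list, were higher in all DSS libraries than in all controls. Sox4 was at 87.6 ± 19.3 against 34.1 ± 25.8 CPM and Tcf7l2 at 63.6 ± 7.65 against 40.1 ± 10.8 CPM (edgeR adjusted p = 0.37 and 0.40). No other of the 23 genes was higher in this way, and 1 was lower in all DSS libraries. This share was not above the 16.7% of all tested genes whose groups did not overlap. Ephb2 of the same list was lower in DSS, at 201 ± 67.7 against 285 ± 43.9 CPM, with overlap between the groups (edgeR adjusted p = 0.53). Neither the crypt base stem cell list (23 genes, median 0.10, camera adjusted p = 0.52) nor the destruction complex and tankyrase list (22 genes, median 0.18, adjusted p = 0.54) passed. Without control replicate 3, the Wnt target and stem cell lists passed camera as higher in DSS at the preset correlation, with medians of 0.41 (adjusted p = 0.021) and 0.47 (adjusted p = 0.017). The correlations estimated for these lists with all 6 libraries, 0.246 and 0.415, were far above that preset. Sox4, Tcf7l2, Lgr4 and Apc, a scaffold of the destruction complex, passed as higher without control replicate 3 too, with log2 fold changes of 2.19, 0.91, 1.47 and 1.27 (adjusted p = 0.029, 0.038, 0.032 and 0.032). The lists of Wnt ligands and receptors (19 genes, median 0.085), SOX factors (7 genes, 0.67), Notch signalling (15 genes, 0.21) and BMP and TGF-β signalling (14 genes, -0.051) had camera adjusted p = 0.95, 0.52, 0.099 and 0.71. The Notch list passed as higher without control replicate 2 (median 0.28, adjusted p = 0.011). Of the BMP and TGF-β list 1 member passed as higher when adjusted over the list alone. The mean of the Wnt ligand and receptor list was -0.063, opposite in sign to its median, and Fzd9 of this list passed adjusted over the list alone (log2 fold change -2.73). Lgr4, a receptor for R-spondins, was at 75.4 ± 36.8 CPM in control and 151 ± 10.4 CPM in DSS (adjusted p = 0.35). Of the secreted Wnt antagonists, 2 were tested, with a median of -0.24. The fetal-like and regenerative list did not pass (22 genes, median 0.17, camera adjusted p = 0.42), and 2 members passed adjusted over the list alone, 1 higher and 1 lower. It passed as higher without control replicate 2 (median 0.30, adjusted p = 0.045) and without DSS replicate 1 (0.23, adjusted p = 0.021). Its member Ly6a, known as Sca-1, was at 21.9 ± 5.78 CPM in control and 89.5 ± 67.1 CPM in DSS (log2 fold change 2.03, edgeR adjusted p = 0.22, DESeq2 adjusted p = 6.6e-04). Its log2 fold change was 1.23 without DSS replicate 2. Ccn1, a target of YAP, was lower (-2.70, edgeR adjusted p = 0.11).

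Antimicrobial and epithelial defence genes were higher in DSS as a list (22 genes, median 0.57, camera adjusted p = 0.033, and adjusted p = 0.83 with an estimated correlation). No member passed over all genes, and 8 passed adjusted over the list alone, 6 higher and 2 lower. The call was lost without control replicate 3, where the median was 0.31 (adjusted p = 0.77), and among genes with at least 50 counts in 3 libraries, where it was 0.48 (adjusted p = 0.057). Duoxa2, which matures the hydrogen peroxide-producing oxidase DUOX2, was at 4.72 ± 3.00 CPM in control and 34.8 ± 21.7 CPM in DSS (log2 fold change 2.88, SE 0.574, edgeR adjusted p = 0.12, DESeq2 adjusted p = 1.9e-06). Nos2, the inducible nitric oxide synthase, had 4, 2 and 0 counts in control replicates 1 to 3 and 52, 506 and 119 counts in the DSS libraries. Wfdc2, a secreted protease inhibitor, was lower, at 72.6 ± 44.5 and 17.4 ± 3.70 CPM.

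The 7 tested MHC class II genes were all higher in DSS (median 1.60, camera adjusted p = 0.0020, and adjusted p = 0.87 with an estimated correlation). None passed over all genes or adjusted over the list alone, and the list call was lost without control replicate 3, where the median was 1.10 (adjusted p = 0.25). Cd74, the invariant chain, was at 3.47 ± 2.94 CPM in control and 18.6 ± 12 CPM in DSS, with overlap between the groups. The lists of MHC class I (15 genes, median 0.19), interferon-stimulated (32 genes, -0.19) and cytokine and chemokine genes (7 genes, 0.41) had camera adjusted p = 0.12, 0.42 and 0.34. The MHC class I list passed as higher without control replicate 1 (median 0.29, adjusted p = 0.034), control replicate 2 (0.32, adjusted p = 0.0055) or DSS replicate 1 (0.34, adjusted p = 0.0036), and with scaling on epithelium genes (0.62, adjusted p = 0.0088).

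Of the genes listed for other cell types, most were absent from the tables or too low to test. Of 25 neutrophil genes 1 was tested, Ly6g, at 1.02 ± 0.762 CPM in control and 12.6 ± 13.5 CPM in DSS (edgeR adjusted p = 0.25). Its DSS mean was raised by replicate 2, at 28.1 CPM against 4.95 and 4.59 CPM in replicates 1 and 3. The lists of monocytes and macrophages (8 genes tested, median 0.37), T and NK cells (7, 0.67), B and plasma cells (5, -0.069), fibroblasts (11, 0.23), endothelium (5, -0.26) and smooth muscle (5, 0.26) had camera adjusted p = 0.30, 0.34, 0.69, 0.54, 0.52 and 0.92. The monocyte and macrophage list passed as higher without control replicate 1 (median 0.57, adjusted p = 0.0015), control replicate 2 (0.56, adjusted p = 0.0023) or DSS replicate 1 (0.73, adjusted p = 0.010). The T and NK cell list did so without control replicate 2 (1.28, adjusted p = 3.1e-04) or DSS replicate 1 (0.77, adjusted p = 0.0017). Adjusted over the list alone, 2 fibroblast genes (1 higher, 1 lower), 1 B and plasma cell gene (higher), 1 endothelial and 1 smooth muscle gene (both lower) passed. For B and plasma cells the camera direction was up, against a negative median and mean. Mast cells and eosinophils (4 genes tested, median 0.92), red cells and platelets (4, 0.079) and mesothelium and fat (1, 0.15) were below the number of genes for a test, and 2 mast cell and eosinophil genes passed as higher adjusted over the list alone. Enteric glia and neuron genes were higher as a list (5 genes, median 1.31, camera adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation), and 2 passed adjusted over the list alone. Its members Gfra3 and Ret, receptors for GDNF family ligands, were at 5.77 ± 2.34 and 7.05 ± 0.594 CPM in DSS and at 1.73 ± 0.656 and 2.83 ± 1.55 CPM in control. The list missed the threshold with a similar or larger median without DSS replicate 3 (1.28, adjusted p = 0.070) and with scaling on epithelium genes (1.48, adjusted p = 0.051). Fbln1, an extracellular matrix gene of the fibroblast list, was at 8.03 ± 2.85 CPM in control and 34.6 ± 1.80 CPM in DSS (log2 fold change 2.11, SE 0.299, edgeR adjusted p = 0.095, DESeq2 adjusted p = 2.3e-07).

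The 13 mitochondrially encoded genes were all lower in DSS after scaling (median -0.98, camera adjusted p = 3.7e-07, and adjusted p = 0.87 with an estimated correlation). None passed over all genes or adjusted over the list alone. ND5, a subunit of complex I, was at 21220 ± 9172 CPM in control and 8645 ± 1232 CPM in DSS (edgeR adjusted p = 0.33). The nuclear-encoded respiratory chain (29 genes, median -0.071), fatty acid oxidation (25, -0.20), hypoxia and glycolysis (24, -0.031), xenobiotic metabolism (28, 0.047) and ribosomal protein lists (31, 0.039) had camera adjusted p = 0.69, 0.099, 0.47, 0.94 and 0.54. The respiratory chain list passed as lower without control replicate 3 (median -0.29, adjusted p = 0.0092). Fatty acid oxidation genes passed as lower without control replicate 2 (-0.20, adjusted p = 0.011), control replicate 3 (-0.36, adjusted p = 0.023) or DSS replicate 3 (-0.39, adjusted p = 0.0023). Ribosomal protein genes passed as higher without control replicate 2 (0.21, adjusted p = 0.011) and with scaling on epithelium genes (0.50, adjusted p = 0.0054), and xenobiotic metabolism genes without DSS replicate 2 (0.41, adjusted p = 0.037). Of the hypoxia list 2 members passed as higher when adjusted over the list alone, and none of the other lists of this group. For the hypoxia list the camera direction and the mean were positive, and for the xenobiotic list the camera direction was down against a positive median and mean. Egln3, an oxygen-sensing prolyl hydroxylase, was at 13.4 ± 1.02 CPM in control and 41.0 ± 10.4 CPM in DSS (log2 fold change 1.61, edgeR adjusted p = 0.097, DESeq2 adjusted p = 4.4e-05). The retinoic acid-forming enzyme gene Aldh1a3 was at 0.723 ± 0.236 and 10.1 ± 12.5 CPM (edgeR adjusted p = 0.23, DESeq2 adjusted p = 3.9e-05). Its log2 fold change was 3.78, and 1.98 without DSS replicate 2.

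Of the remaining lists none passed with all 6 libraries. They were absorptive colonocyte (33 genes, median -0.12, camera adjusted p = 0.41), general epithelium (24, -0.24, 0.32), small intestine enterocyte (12, 0.090, 0.32), ion and water transport (24, -0.066, 0.38), tight junction (19, -0.033, 0.54), mucin glycosylation (23, 0.16, 0.88), ER stress (25, -0.058, 0.32), cell death (28, 0.057, 0.69), matrix protease (7, -0.13, 0.79) and cell cycle genes (32, 0.16, 0.74). The tight junction and matrix protease lists had a positive mean and camera direction against a negative median, while the cell death and mucin lists had a negative mean and, for cell death, a negative camera direction. Adjusted over the list alone, 2 small intestine genes and 1 matrix protease gene passed as higher, 2 ER stress and 3 cell death genes as lower, and 3 ion and water transport genes, 1 higher and 2 lower. Colonocyte genes passed as lower without DSS replicate 3 (median -0.70, adjusted p = 0.0042), general epithelium genes without control replicate 3 (-0.42, adjusted p = 0.018) and ER stress genes without control replicate 1 (-0.24, adjusted p = 0.0017), and small intestine genes passed as higher without DSS replicate 2 (0.18, adjusted p = 0.030). The cell cycle result depended on single libraries as well: its median was -0.54 without DSS replicate 2 (camera adjusted p = 2.1e-06) and 0.46 without DSS replicate 3 (adjusted p = 0.0048). Both calls were at the preset, and the correlation estimated for the cell cycle list with all 6 libraries was 0.864. The chloride channel gene Ano1 was at 107 ± 17.4 CPM in control and 34.0 ± 14.0 CPM in DSS (log2 fold change -1.66, edgeR adjusted p = 0.11, DESeq2 adjusted p = 1.5e-04). The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4, similar copies between which reads may be split, had log2 fold changes of -1.71, -1.75 and -1.77 (edgeR adjusted p = 0.11, 0.22 and 0.15), and DESeq2 called all of them (adjusted p = 9.1e-05, 0.0016 and 1.9e-04).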

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

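The tests with the newer edgeR method and without mitochondrial genes and Muc2 were chosen after the data were seen. The count of 5 changed genes (0 higher, 5 lower) was also 5 with RLE and upper quartile scaling, a robust prior, at least 50 counts in 3 libraries and without mitochondrial genes and Muc2, and in these settings the same 5 genes were called. It was 6 with limma-voom, 4 of them shared, and 4 for protein-coding genes alone and for the test against a log2 fold change of 1. DESeq2 gave 281 (97 higher, 184 lower) and no filter on low counts 339 (114 higher, 225 lower). Library totals and epithelium scaling each gave 1, lower in DSS; they moved log2 fold changes by medians of 0.29 and 0.33, and FPKM by 0.28 to 0.30. With epithelium scaling the medians of 13 lists that were not called changed sign. FPKM with a pseudocount of 1 gave 10 (2 higher, 8 lower), with 0.1 it gave 8 (2 higher, 6 lower), and without a filter 0, where 2343 genes had an unadjusted p under 0.05. An adjusted p of 0.01 gave 1, lower, and the newer edgeR method 8, all lower. The cause of these changes was not tested, apart from the stricter threshold. Leaving out 1 library gave 0 to 1042 genes, 0 to 553 higher and 0 to 489 lower. The highest values came without control replicate 3 and the 0 without DSS replicate 1, 2 or 3, where 962 to 1247 genes had an unadjusted p under 0.05. The 5 genes kept their direction in each of these fits.

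Nothing in the labels says that the replicate numbers pair mice. Same-numbered libraries deviated from their group means with correlations of -0.11, 0.31 and -0.0042, and differently numbered ones with -0.28 to 0.31. With 3 libraries per group these values cannot show whether the numbers pair mice, so pairing stays unknown. With the number as a block, 70 genes passed (15 higher, 55 lower) and 8 lists.

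The count of 8 lists was 0 with an estimated correlation, 0 with fry, 5 with at least 50 counts in 3 libraries, where 31 lists were tested, 9 with epithelium scaling and 7 without mitochondrial genes and Muc2. At the preset, leaving out 1 library gave 9 to 14 lists, the highest without control replicate 2. Cell cycle genes reversed without DSS replicate 2 (median -0.54, range -0.54 to 0.46 over the left-out libraries). Xenobiotic metabolism genes were called as higher there (median 0.41, range -0.687 to 0.666). No named gene passed the threshold in opposite directions under any of these alternatives. Most genes of the immune and stromal lists had too few counts to test or were not in the tables, and whether depth or a low content of these cells set this was not tested.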

Other observations

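The tests of handling stress, time of day, count shares, goblet cell number and a wrong label were chosen after the results were seen, the test of other splits before, and the test of colon segment after the main results but before any value of its genes was seen. The criteria for handling stress and a wrong label were made more cautious, leaving both open, after their values were seen, because the members of the dissociation list went both ways and the position of control replicate 3 differed between gene groups. Outside the lists fixed beforehand, 13 clock genes were chosen after their values were seen, and in 6 of them the groups overlapped. All 9 tested genes of the PER arm were higher in DSS, with a median log2 fold change of 1.45. In 6 of them the groups did not overlap, against 16.7% of all tested genes. Because the genes were picked for their values, these counts restate the choice and test nothing. Per2, a repressor of the clock, was at 16.9 ± 3.29 CPM in control and 62.1 ± 27.7 CPM in DSS (log2 fold change 1.88, edgeR adjusted p = 0.12, DESeq2 adjusted p = 1.1e-04), and Ciart at 0.870 ± 0.546 and 4.67 ± 2.35 CPM. Of the 4 genes of the BMAL1 arm 3 were lower (median -0.93), with Npas2 at 30.3 ± 12.1 and 7.39 ± 4.55 CPM (edgeR adjusted p = 0.20, DESeq2 adjusted p = 6.3e-04) and Arntl, whose groups overlapped, at 28.1 ± 9.13 and 13.4 ± 4.56 CPM. No clock gene passed with edgeR over all genes. Of 360 KEGG pathways as the tables annotate them, 1, annotated as cocaine addiction, passed camera at its preset (29 genes, median -0.21, adjusted p = 0.037), and its adjusted p was 0.99 with an estimated correlation.

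Immediate early and heat shock genes, mostly lower in DSS, and the clock genes picked for their values were examined together as a first pattern. An unequal share of mitochondrial and Muc2 counts was examined for the immediate early list with counts scaled to library totals. Leaving these genes out moved the median of all genes by -0.18 and that of the list from -1.83 to -2.02, with a bootstrap standard error of 0.680. Their mean share was larger in control, so leaving them out had to lower log2 fold changes, and the direction tests nothing. The values show the size alone: the shift of all genes was small beside the list median of -1.83. A difference in the time of day of collection was neither supported nor excluded: the medians of the 2 clock arms differed by 2.38, as did 0.01% of 10000 random pairs of lists matched on expression, the smallest value they can give, but genes chosen for their shift can only restate it. Handling stress in the control crypts cannot be told apart from an effect of DSS, because 79 other genes known to be induced by tissue dissociation went both ways (44 higher, 35 lower) and 92.4% of random lists had a median as low. Collection time and handling are not recorded in the labels, so an effect of DSS on either gene group stays open.

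Goblet and deep crypt secretory genes, mostly lower in DSS, were examined as a second pattern. None of them passed over all genes, and neither list call held with an estimated correlation. The test of goblet cell number assumed that a loss of these cells lowers all their listed genes alike, which was not checked. The SD of log2 fold changes over the goblet list was 3.44 times that of the epithelium list. Its bootstrap interval of 1.18 to 5.99 leaves the question open. A different colon segment cannot be told apart from an effect of DSS either, because 2 of 7 genes of the distal gut axis were expressed enough to test, with a median of -0.34 and a standard error of 0.457, and these are too few to bear the bound set before their values were seen. Of these, Hoxa13 had a log2 fold change of 0.31 and Hoxb13 of -0.98, and Hoxb13 differed widely between mice, at 118, 282 and 68.3 CPM in control replicates 1 to 3 and 37.0, 198 and 1.91 CPM in DSS replicates 1 to 3. A response of these cells to DSS was not tested separately.

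Control replicate 3 lay closer to DSS replicate 1 than to the other controls. Over 1040 genes called without it, its median position was 0.924 on a scale from the mean of the other controls (0) to the DSS mean (1), and 85.2% of the genes lay nearer to DSS. Over the 19 immediate early and heat shock genes its median position was 0.207, on the side of the controls. Clca1, at 1176 CPM against 25 to 71.5 CPM in DSS, Mptx1, with 11346 counts against 4, 159 and 0, Trpm5, at 43.0 against 0.589 to 10.1 CPM, Gm10382, at 30.0 against 1.77 to 3.53 CPM, Npas2, at 36.0 against 4.41 to 12.6 CPM, and Per2, at 19.6 against 31.4 to 85.3 CPM, were on that side too, though these were picked among genes that separate all controls from DSS. A wrong label cannot be told apart from a true control mouse in a state shared with DSS libraries, because these gene groups point to opposite sides and the 1040 genes were selected on the other controls.

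The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5 genes and the highest other split 0, so 1 of the 10 reached that count. For the lists, the real split gave 8 and the highest other 17, and all 10 splits gave at least 8. The list calls at the preset correlation of 0.01 thus do not set the real groups apart from other groupings. The estimated correlation among members was 0.499 for the immediate early, 0.706 for the tuft and 0.939 for the mitochondrial list, and whether this or a structure among the libraries raised the counts was not tested.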
